A study of Mus musculus with 6 samples.

How the data were processed

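Gene expression was measured by RNA sequencing in the prefrontal cortex of 6 samples, 3 from single-housed and 3 from group-housed wild-type mice, after 6 days of housing. Per the labels' protocols, RNA was isolated with a column kit (RNeasy) and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps strand. Per the submitters' processing notes, FastQC, STAR and featureCounts were used with mouse build mm9; their versions, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited values are raw counts of reads per gene, 1 column per library, with no normalization by the authors, in the column layout of featureCounts per the file headers. The deposited length column gives the summed exon bases of a gene, per the file headers, and was not used in any test. Because the strand setting is not given, counts of genes that overlap an antisense gene cannot be assigned with certainty, and reads shared between near-identical copies may have been dropped: Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2 are listed at 0, while the beta-globin gene Beta-s has counts, and the 13 mitochondrially encoded genes of the fixed list have no row, so no mitochondrial share was computed. Coordinates are those of the deposited table in mm9. The reference annotation at hand was of another build and served only for names: 5 list members were matched through an older symbol and 18 were not matched.

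Samples were assigned to groups by the housing label, and replicate numbers were taken from the titles. Total counts ranged from 25858355 to 33428512 per library. The low counts filter (filterByExpr, minimum count 10, minimum total count 15) kept 15258 of 23284 genes, while 4186 genes had 0 counts in every library; the genes left out held 0.0253% to 0.0306% of each library's counts. A floor of 3 counts is given where a gene had 0 counts, and it covers counting error only. Chi-square per degree of freedom between libraries was 9.79 to 38.7 within groups and 8.21 to 27.5 between groups, so no pair agreed within sampling noise, and the correlation of log2 CPM across genes, which are not independent replicates, was 0.987 to 0.995 between libraries. Xist had 1 to 5 counts and the Y-linked gene Ddx3y 1393 to 1933 counts in each library.

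The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) on the counts as deposited, with TMM normalization, Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 differences were derived from the F statistic, and the common biological coefficient of variation was 11.8%. Gene lists were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 26 of 30 lists that had at least 5 measured genes, then with a correlation estimated per list and with fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes. List means per library were compared by an exact two-sided permutation test, whose smallest p is 0.1. The lists, the tests, the named-gene rule and the first set of alternatives were chosen before the data were examined. The rule named up to 10 genes per direction that passed the threshold with groups that did not overlap, filled to 5 by unadjusted p where fewer passed and skipping predicted genes, the 3 genes of smallest p from each of 7 primary lists and from each list past the list test, and 12 genes fixed by name; some genes that the rule names are not reported here. A list of 7 further striatal genes was written after a first look at the data. Reactome sets (865 with 10 to 300 measured genes, from fgsea 1.28.0) were tested with camera as an exploration.

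On data simulated from the means and library sizes of these samples (15258 genes, 5 simulations, 250 changed genes per fold size), the gene test recovered 52.0% of 1.5-fold, 84.8% of 2-fold, 95.6% of 4-fold and 99.6% of 8-fold changes with 61 false calls in all. A list lowered 1.4-fold was called in 5 of 5 simulations, and 0 of 125 tests of other lists were called. The simulated genes were independent of each other, which real genes are not. The simulations also held no differences in tissue between libraries of a group. The shares recovered may therefore be too high for these samples, in which Egr2 (log2 difference −1.74) did not pass the gene test. The first set of alternatives was DESeq2 size factors, no filter, a filter at a mean CPM above 1, leaving out each library, the replicate number as a block, DESeq2 (1.42.0), limma-voom and robust empirical Bayes. Alternatives added after seeing the data were the striatal list mean as a covariate, the fit without the 3 libraries with high striatal markers, and lists without the members they share with the immediate early or striatal lists.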

Results

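RNA from the prefrontal cortex of wild-type C57BL/6 mice, an inbred laboratory strain, was sequenced after 6 days in which the animals lived either alone or in groups. There were 3 libraries from single-housed and 3 from group-housed mice, aged 8 to 10 weeks. The deposited values were raw read counts for 23284 gene symbols. Total counts were 32902303, 33176093 and 33428512 in single-housed replicates 1, 2 and 3, and 25858355, 30931952 and 32088512 in group-housed replicates 1, 2 and 3. Each single-housed library was deeper than each group-housed library (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Between 17750 and 17836 genes had a count in each single-housed library and between 17634 and 17695 in each group-housed library (exact two-sided permutation p = 0.1). The labels do not say that each library came from its own mouse, so p-values measure the spread between these samples, which may be partly technical. The design compares the 2 housing conditions, under a series title that concerns interferon-gamma, neuronal connectivity and social behaviour. All differences are given as single-housed minus group-housed on the log2 scale, with levels as CPM, the count scaled to a common library total (by TMM unless stated as of the total).

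Immediate early genes, which neurons transcribe within minutes of being active, were lower in the single-housed mice. Of the 26 members measured, 25 had a lower level in the single-housed group, with a median log2 difference of −0.49. The mean log2 CPM over the list was 4.69 ± 0.121 in single-housed and 5.27 ± 0.173 in group-housed libraries (SD, n = 3 each), which is 1.49-fold higher with company. Each single-housed library lay below each group-housed library (exact two-sided permutation p = 0.1, the smallest possible). The list passed the list test (camera, adjusted p = 3.87e-26; 0.0195 with an estimated correlation; fry adjusted p = 0.0321). The exception in direction was Nr4a2, an orphan nuclear receptor gene, at 27.2 ± 16.8 against 18.8 ± 6.80 CPM, chosen after its values were seen.

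Fosb and Fos encode subunits of the AP-1 transcription factor, and Egr2 and Egr4 encode zinc-finger transcription factors. Fosb (chromosome 7, 19888045 to 19895394, mm9) was at 11 ± 0.781 CPM in single-housed and 18.0 ± 0.669 CPM in group-housed libraries (log2 difference −0.71, SE 0.0941, n = 3 each). Egr2 (chromosome 10, 67000617 to 67004936) was at 3.22 ± 0.284 against 10.7 ± 3.71 CPM (−1.74, SE 0.250). Egr4 (chromosome 6, 85461116 to 85463536) had a difference of −0.85 (SE 0.146), and Fos (chromosome 12, 86814851 to 86818219) one of −1.42 (SE 0.265), from 36.1 ± 14.7 CPM with company to 13.5 ± 2.04 CPM alone. Arc (chromosome 15, 74499513 to 74503000), which encodes a postsynaptic protein that controls glutamate receptor trafficking, was at 79.5 ± 36.4 against 219 ± 121 CPM (−1.46, SE 0.416; −0.91 without group-housed replicate 1). Over all genes tested, none of the 26 passed edgeR's quasi-likelihood test. Adjusted over the list alone, 11 were lower, namely Fosb, Egr2, Egr4, Fos and Arc and, named after their values were seen, Egr1, Ier5, Nr4a1, Dusp6, Nptx2 and Junb. Leaving out 1 library kept the list past the threshold with the preset correlation. With an estimated correlation the adjusted p was 0.0382 without single-housed replicate 2 but 0.130 and 0.110 without single-housed replicates 1 and 3. It was 0.145, 0.0704 and 0.0799 without group-housed replicates 1, 2 and 3. Markers of the striatum, the region beneath the frontal cortex, also differed between libraries. With their mean as a covariate, chosen after the data were seen, the immediate early list mean differed by −0.63 (SE 0.128, against −0.58, SE 0.122, without it), with an adjusted p of 0.108 with an estimated correlation.

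**Figure D1:**
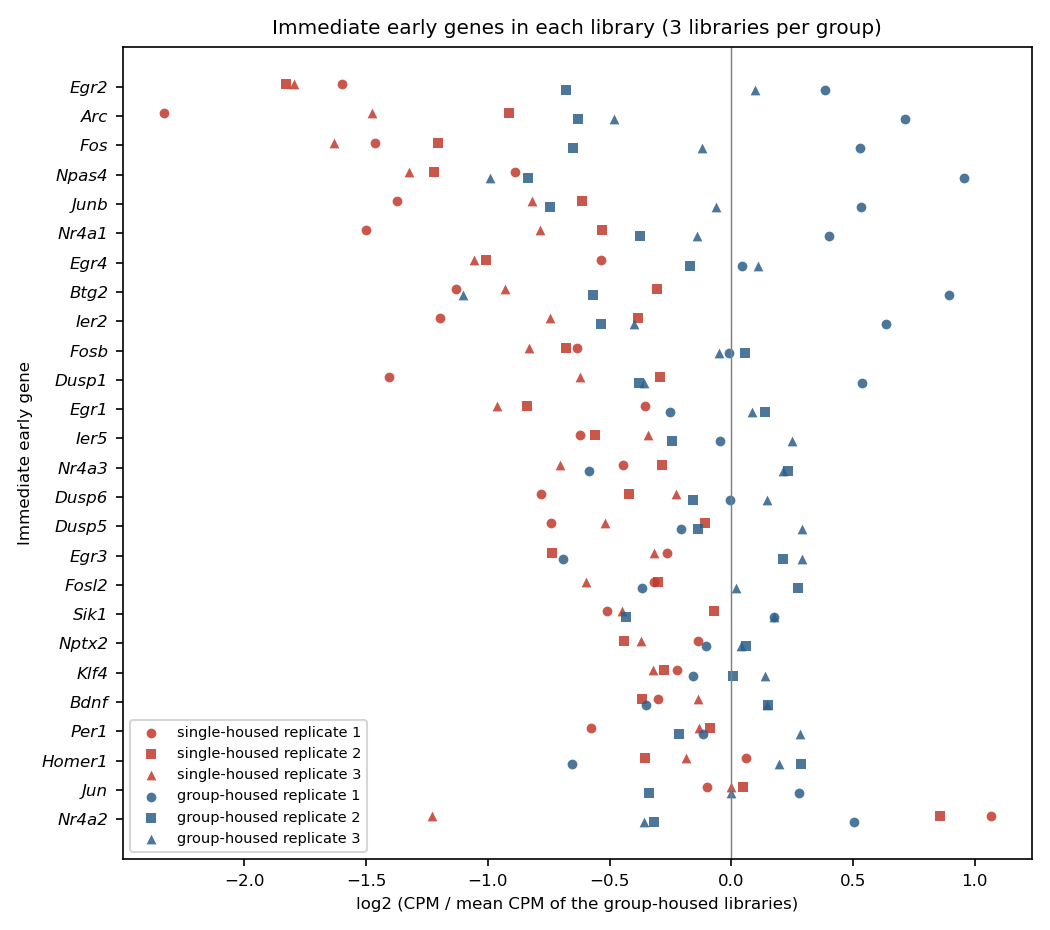
Level of each of the 26 immediate early genes in each library, as the log2 ratio of its CPM to the mean CPM of the 3 group-housed libraries (horizontal axis); red points are single-housed and blue points group-housed libraries, with 1 symbol per replicate. Fosb shows 3 red points left of 3 blue ones, and Nr4a2 is the gene whose single-housed mean was higher.

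Outside the immediate early genes, the genes of smallest p did not pass the gene test. Htr2c, the serotonin 2C receptor gene, was at 26.8 ± 4.06 CPM in single-housed and 18.2 ± 0.833 CPM in group-housed libraries (chromosome X, 143397056 to 143631820; 0.56, SE 0.120, n = 3 each). Ndst4, a heparan sulfate-modifying enzyme gene, was low and uneven, at 2.54 ± 1.83 against 0.418 ± 0.103 CPM (chromosome 3, 125107009 to 125427904; 2.59, SE 0.595). Its difference was 1.92 without single-housed replicate 2 and 0.94 without the 3 libraries with high striatal markers, which leaves 1 library against 2. Lmo7 (chromosome 14, 102129145 to 102333910) and Abi3bp (chromosome 16, 56477959 to 56690248) had differences of 0.33 (SE 0.0817) and 0.64 (SE 0.165). On the lower side, outside the immediate early genes, the myosin heavy chain gene Myh13 was at 0.422 ± 0.0893 against 1.04 ± 0.173 CPM (chromosome 11, 67140605 to 67185004; −1.28, SE 0.268). These 5 genes, with Fosb, Egr2, Egr4 and Fos, were among those with the smallest p-values in their direction among genes whose groups did not overlap, and none passed the threshold.

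Of 15258 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 were higher and 0 were lower, and the smallest adjusted p was 0.606, for Fosb and Egr2. At an unadjusted p under 0.05 there were 127 higher and 111 lower genes, 238 in all, where 762.9 would be found by chance. The groups did not overlap for 742 genes, 4.86% of those tested, against 10% by chance for 3 against 3. The main axis of variation between libraries (first principal component) held 45.7% of the variance. It followed the striatal list mean (correlation −0.95), with libraries of both groups on either side. With that mean as a covariate, 429 genes had an unadjusted p under 0.05 for housing. Differences within a group enter the error of the housing test, so 0 calls do not show that housing has no effect. DESeq2 called 8 genes, 6 lower (Egr2, Fos, Egr1, Egr4, Fosb and Nptxr) and 2 higher, among them Ndst4, and limma-voom called 0. Nptxr, a neuronal pentraxin receptor gene, was also the 1 gene called by edgeR without group-housed replicate 1, and Egr2 the 1 called without group-housed replicate 2. Nptxr and Egr1 were named after their values were seen.

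Interferon-gamma response genes showed no common shift with housing past the threshold. Of 38 measured, 23 were lower and 15 higher in single-housed libraries, with a median log2 difference of −0.05 (camera adjusted p = 0.130; 0.717 with an estimated correlation), and 0 passed either over all genes or adjusted over the list alone. The list mean was 2.08 ± 0.0281 against 2.10 ± 0.0926 log2 CPM (SD, n = 3 each; exact two-sided permutation p = 0.7). The members with the smallest p were H2-Eb1, a class II antigen presentation gene (−0.38, SE 0.195), B2m, the light chain of class I molecules (−0.17, SE 0.0858), and Irgm2, an immunity-related GTPase (−0.24, SE 0.153). Ifng itself had 0 counts in all 6 libraries, where 3 counts would be 0.0897 to 0.116 CPM of the total, so its transcript was not detectable at this depth. Such a floor covers counting error only. Cxcl10, an interferon-induced chemokine gene, had 0 to 4 counts per library and was not tested. Without group-housed replicate 2 the interferon-gamma list was called lower (adjusted p = 0.00897), but 0 lists were called in that fit with an estimated correlation.

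The interferon-gamma receptor genes Ifngr1 and Ifngr2 and the response regulator Irf1 differed by less than the spread between replicates. The receptor subunits were at 16.8 ± 0.733 against 16.3 ± 2.27 CPM and 47.8 ± 2.80 against 47.2 ± 3.99 CPM, with log2 differences of 0.05 (SE 0.114) and 0.02 (SE 0.0861). Irf1, a transcription factor gene of the response, had a difference of −0.09 (SE 0.149). Over the 12 receptor and JAK-STAT genes, 9 were higher and 3 lower (adjusted p = 0.975), with a median of 0.02 and a mean of −0.03; Socs1 (−0.43, SE 0.364), Tyk2 (0.10, SE 0.101) and Socs3 (−0.22, SE 0.232) had the smallest p. Of 30 type I interferon response genes, 19 were lower and 11 higher (median −0.04, adjusted p = 0.167), among them Irf7 (−0.51, SE 0.202), Oasl2 (0.43, SE 0.191) and Eif2ak2 (0.23, SE 0.124). The groups did not overlap for 4 of these 30 genes, among them Irf7 and Eif2ak2, which went in opposite directions. Chance gives 10% of genes, and the share over all genes tested was 4.86%. Adjusted over the list alone, 0 genes of either list passed.

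Glucocorticoid-responsive genes were lower as a list, with 17 of 20 members lower and a median log2 difference of −0.13 (camera adjusted p = 9.87e-04), but the call was lost with an estimated correlation (adjusted p = 0.137) and without group-housed replicate 2 (0.0569). Cdkn1a, a cell cycle inhibitor gene, was at 27.8 ± 3.32 against 37.3 ± 8.42 CPM (−0.42, SE 0.167). Dusp1, a phosphatase gene also among the immediate early genes, was at 20.1 ± 7.25 against 32.8 ± 12.8 CPM (−0.70, SE 0.312). Its difference was −0.33 without group-housed replicate 1. Sult1a1, a sulfotransferase gene, was at 4.17 ± 0.386 against 5.50 ± 1.27 CPM (−0.40, SE 0.180), and its difference was −0.21 without group-housed replicate 2. Fkbp5, the glucocorticoid receptor co-chaperone gene, was at 34.0 ± 2.07 against 32.9 ± 3.49 CPM (0.05, SE 0.0989). Heat shock and unfolded protein response genes were lower in 25 of 27 cases by small amounts (median −0.10, adjusted p = 1.14e-05; 0.611 with an estimated correlation), with Sdf2l1 (−0.32, SE 0.108), Dnajb5 (−0.21, SE 0.0999) and Creld2 (−0.20, SE 0.0961) in front. That call was lost without group-housed replicate 3 (adjusted p = 0.208). None of these genes passed adjusted over the list alone.

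Genes of inhibitory transmission and myelin had no shared direction past the threshold. Of 23 GABA receptor subunit and synthesis genes, 16 were higher and 7 lower (median 0.04, adjusted p = 0.223; called higher without group-housed replicate 2, 0.0116, and with the striatal covariate, 0.0165, where an estimated correlation gave 0 called lists and an adjusted p of 0.676 respectively), with Abat (0.13, SE 0.0959), Gabra4 (0.12, SE 0.0896) and Gad2 (0.11, SE 0.0986) having the smallest p. Gad1, which encodes the main GABA-synthesising enzyme, was at 400 ± 29.7 against 387 ± 9.97 CPM (0.04, SE 0.0766). Of 25 myelin and oligodendrocyte genes, 18 were lower and 7 higher (median −0.05, adjusted p = 0.699), including Enpp2 (−0.10, SE 0.0678), Olig2 (−0.12, SE 0.182) and Olig1 (−0.10, SE 0.247). Mbp, myelin basic protein, was at 1092 ± 413 against 1114 ± 567 CPM (−0.03, SE 0.378), an error wide enough that a moderate difference was not detectable. The myelin list was called higher without group-housed replicate 1 (adjusted p = 0.00117) or single-housed replicate 3 (0.00400), and lower without group-housed replicate 2 (0.00165), with the striatal covariate (5.54e-15; 0.672 with an estimated correlation) and without the 3 libraries with high striatal markers (1.53e-05, 1 library against 2). With an estimated correlation, 0 lists were called in the fits without group-housed replicate 1, group-housed replicate 2 or single-housed replicate 3.

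Striatal markers were higher in the single-housed group for 18 of 18 genes (median 0.96, camera adjusted p = 1.14e-05). This call was lost with an estimated correlation (adjusted p = 0.717), without single-housed replicate 1 (0.320) and without group-housed replicate 2 (0.0544). The list mean was 5.86, 4.82 and 2.75 log2 CPM in single-housed replicates 1, 2 and 3 and 4.76, 2.75 and 3.24 in group-housed replicates 1, 2 and 3 (exact two-sided permutation p = 0.5). Pdyn, the prodynorphin gene (0.31, SE 0.144), Rarb, a retinoic acid receptor gene (0.86, SE 0.428), and Actn2, an actinin gene (0.57, SE 0.295), had the smallest p. Without single-housed replicate 1 the differences of Pdyn, Rarb and Actn2 were 0.17, 0.32 and 0.13. Chosen after their values were seen, Drd2, the dopamine D2 receptor gene, was at 46.8, 17.4 and 0.868 CPM of the total in single-housed replicates 1, 2 and 3 and at 16.7, 1.0 and 2.52 in group-housed replicates 1, 2 and 3. Ppp1r1b, which encodes the dopamine signalling protein DARPP-32, was at 424, 191 and 64.6 against 220, 65.4 and 87.3. Without the 3 libraries with high striatal markers, an alternative chosen after the data were seen, 1 single-housed library was left against 2 group-housed ones. In that fit the lone library is assumed to vary like the other group, and edgeR called 1 gene higher (Capn11) and 3 lower (Arc, Nptxr and Egr1).

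**Figure D2:**
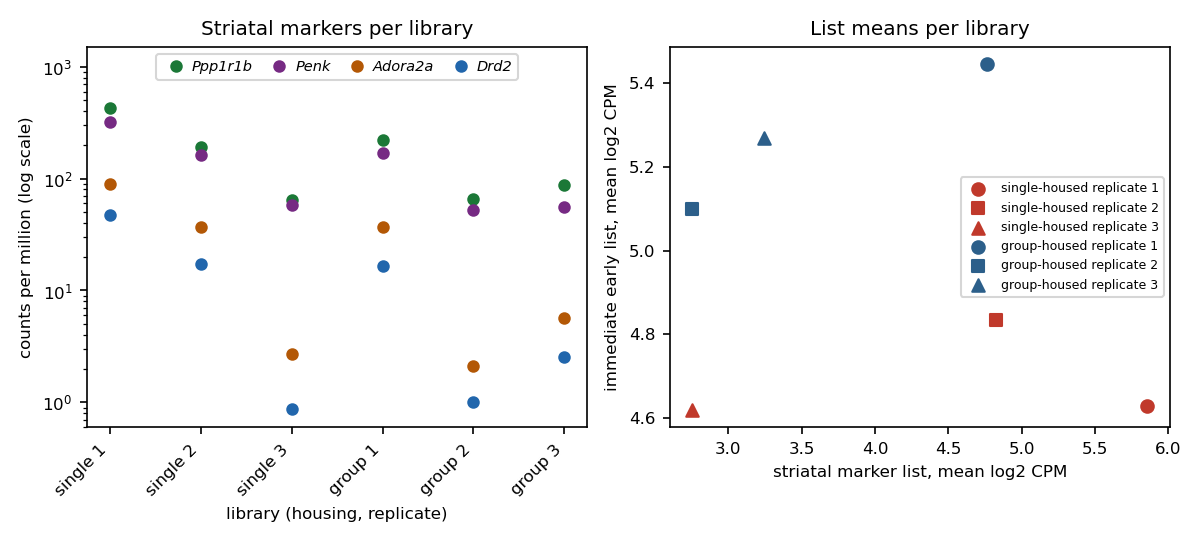
Left, CPM of the total (log axis) of 4 striatal genes in each library; right, mean log2 CPM of the immediate early list (vertical axis) against that of the striatal list (horizontal axis), with 1 point per library, red for single-housed and blue for group-housed. Drd2 lay between 0.868 and 46.8 CPM, high in single-housed replicates 1 and 2 and group-housed replicate 1, while all 3 single-housed libraries lay below all 3 group-housed ones on the immediate early axis.

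Monoamine and social neuropeptide genes were higher in 20 of 26 cases (median 0.14, adjusted p = 0.00116; 0.137 with an estimated correlation), and 1, Htr2c, passed adjusted over the list alone. Several members of the list are striatal genes, Drd2 and Pdyn among them. With members shared with the striatal or immediate early lists left out, the list was still called with the preset correlation (camera adjusted p = 0.0150, median 0.10 over 22 genes). With the striatal covariate and an estimated correlation the camera adjusted p of the whole list was 0.343. The call was lost with no filter on low counts (0.0558) and without the 3 libraries with high striatal markers (0.187, 1 library against 2). Cartpt, a neuropeptide gene, was at 3.84 ± 0.437 against 3.01 ± 0.395 CPM (0.35, SE 0.161), and Oxtr, the oxytocin receptor gene, at 7.24 ± 0.587 against 6.51 ± 0.158 CPM (0.16, SE 0.111). Fibroblast markers of the meninges and vessels were higher for 15 of 16 genes (median 0.18, adjusted p = 4.15e-04; 0.717 with an estimated correlation), such as Col3a1 (0.36, SE 0.208), Col1a1 (0.27, SE 0.164) and Bgn (0.19, SE 0.115). This call was lost without single-housed replicate 3 (0.107) and without group-housed replicate 1 (0.967). Endothelial markers were higher for 13 of 18 genes (median 0.09, adjusted p = 0.0193; 0.722 with an estimated correlation), with Vwf, the von Willebrand factor gene, at 21.2 ± 3.08 against 15.5 ± 1.88 CPM (0.45, SE 0.133), Kdr at 0.20 (SE 0.130) and Flt1 at 0.16 (SE 0.122). The endothelial call was lost without any 1 of single-housed replicates 1 (0.904) and 3 (0.0969) and group-housed replicates 2 (0.169) and 3 (0.112), with no filter on low counts (0.0558), with the striatal covariate (0.256), and without the 3 libraries with high striatal markers (0.0820).

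Markers of the olfactory bulb and migratory stream were higher for 12 of 14 genes (median 0.14, adjusted p = 0.0282; 0.611 with an estimated correlation), with Synpr at 0.18 (SE 0.0698) and Cdhr1 at 0.57 (SE 0.316). The call was lost without single-housed replicate 1 (0.242) or 2 (0.156) and without group-housed replicate 2 (0.304) or 3 (0.172). It was also lost with no filter on low counts (0.438), with the striatal covariate (0.533) and without the 3 libraries with high striatal markers (0.992). Nuclear genes of oxidative phosphorylation were lower for 48 of 57 members by small amounts (median −0.04, adjusted p = 0.0193; 0.828 with an estimated correlation), among them Cox5a (−0.16, SE 0.0823), Cox8a (−0.11, SE 0.0925) and Uqcr10 (−0.15, SE 0.125). That call was lost without single-housed replicate 3 (0.148), group-housed replicate 3 (0.866) and the 3 libraries with high striatal markers (0.914), and the direction turned without group-housed replicate 1 (0.873). In all, 9 of 26 lists passed with the preset correlation, 5 higher and 4 lower, of which only the immediate early list passed with an estimated correlation or by fry.

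The other lists did not pass the list test. Markers of astrocytes (10 of 16 lower, adjusted p = 0.130), microglia and macrophages (15 of 19 lower, 0.282), oligodendrocyte precursors (8 of 12 lower, 0.699), pericytes and smooth muscle (9 of 12 higher, 0.169), and choroid plexus and ependyma (10 of 13 higher, median 0.26, 0.162) were each spread around small medians except the last. Neuronal markers gave adjusted p-values of 0.504 for glutamatergic neurons (11 of 18 lower, median −0.03 and mean 0.01), 0.472 for GABAergic interneurons (11 of 18 lower) and 0.130 for hippocampus and thalamus (11 of 17 higher). The hippocampus and thalamus list was called with a mean CPM above 1 (camera with the preset correlation, 0.0358). With an estimated correlation its adjusted p in the main fit was 0.611. Ionotropic glutamate receptor genes were higher for 14 of 18 (0.162), synaptic scaffold and adhesion genes for 16 of 26 (0.975, median 0.01, tested direction lower), and circadian clock genes for 10 of 18 (0.975, median 0.03 and mean −0.02). Cytosolic ribosomal protein genes were lower for 42 of 53 (0.130). With the striatal covariate the lists of astrocytes (0.0353), oligodendrocyte precursors (0.0225) and ribosomal proteins (0.00127) were called lower, but not with an estimated correlation (adjusted p = 0.676, 0.672 and 0.676). Leaving out 1 library brought some of these lists past the threshold with the preset correlation: astrocytes without single-housed replicate 1 (0.0284) or group-housed replicate 2 (0.00701), pericytes without single-housed replicate 2 (0.0226), and choroid plexus without single-housed replicate 3 (4.91e-04) or group-housed replicate 3 (0.0261). The same held without group-housed replicate 1 for glutamatergic markers (0.0139), synaptic genes (0.00117), clock genes (0.0466) and, in the other direction, ribosomal genes (0.0340). Without group-housed replicate 2 it held for microglia (0.00365), ionotropic receptors (0.0182), ribosomal genes (1.86e-08) and, in the other direction, synaptic genes (0.0488). None of these calls held with an estimated correlation, with which 0 lists were called without each library except single-housed replicate 2, where the immediate early list was. The lists of T cell, B cell and neutrophil markers (2 genes measured), blood cell markers (4), sex-linked transcripts (4) and mitochondrially encoded transcripts (0) held too few genes to test.

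**Figure D3:**
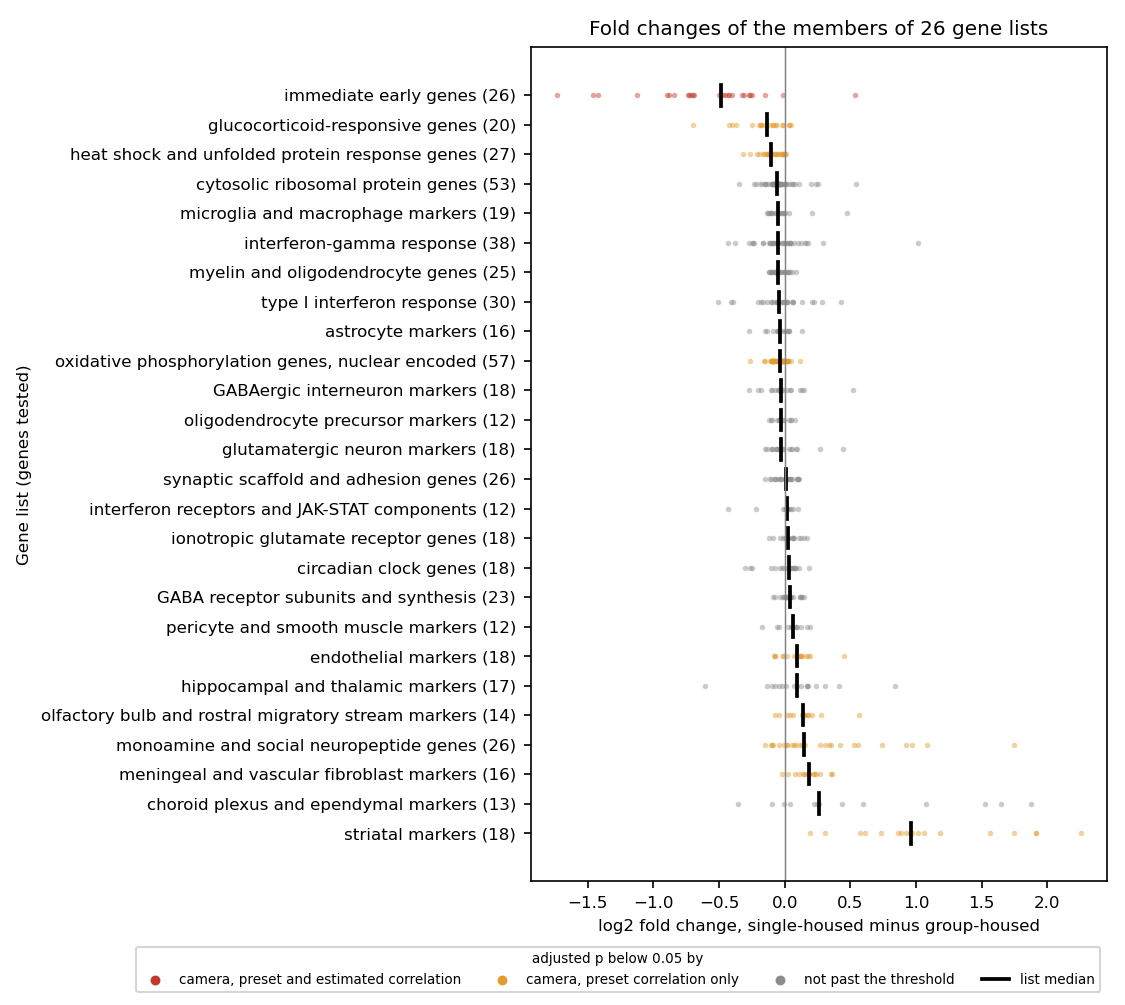
Log2 difference, single-housed minus group-housed (horizontal axis), of each measured gene of the 26 lists tested, with 1 point per gene, the number of genes in parentheses and a black bar at the list median. The immediate early list has its median at −0.49 and is the 1 list past the threshold with both the preset and an estimated correlation; the striatal list has its median at 0.96.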

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

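The striatal covariate, the fit without the 3 libraries with high striatal markers, and the lists without shared members were chosen after the data were seen. The immediate early list was lower with an adjusted p under 0.05 in all 15 alternatives of the list test (2.95e-30 to 0.0321), from 4.30e-28 to 4.84e-15 with 1 library left out; in fits that combined a left-out library, the covariate or the block with an estimated correlation it passed only without single-housed replicate 2. The interferon-gamma list ranged from 0.00897 (without group-housed replicate 2, called lower) to 0.835 with 1 library left out, and this was the 1 alternative in which it was called. Counts of genes were 0 in each direction with edgeR under DESeq2 size factors, either filter change, robust empirical Bayes and the covariate, and with limma-voom; DESeq2 gave 2 higher and 6 lower, and leaving out 1 library 0 higher and 0 to 1 lower. The fit without the 3 high-striatal libraries gave 1 higher and 3 lower, but it sets 1 single-housed library (replicate 3) against 2 group-housed ones, takes its spread from the latter, and is not comparable with the fits of 2 or 3 libraries per group. Lists called were 9, with 6 to 13 when 1 library was left out (6 without group-housed replicate 3, 13 without group-housed replicate 2), against 1 with an estimated correlation and 1 by fry. No scaling moved the median log2 difference of all genes by more than 0.1. The depth of 25858355 to 33428512 counts per library leaves genes such as Ifng under the floor of 3 counts, and 3 libraries per group recovered 52.0% of simulated 1.5-fold changes. Those simulations held no tissue differences between libraries, so that share may be too high for these samples. The cause of the reversals and lost calls below was not tested.

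Replicate numbers were not treated as pairs, because the labels do not say that they pair the mice. Deviations of same-numbered libraries correlated across genes at 0.27, −0.32 and 0.17, and single-housed replicate 3 correlated best with group-housed replicate 2 (0.35). These correlations cannot decide whether the libraries are paired, because their signs followed the striatal markers. Single-housed replicates 1 and 2 correlated positively only with group-housed replicate 1 (0.27 and 0.32), the other library with high striatal markers. With the replicate block edgeR called 0 genes higher and 0 lower, 9 lists passed, and Mbp (0.0027 log2) and the list of interferon receptors (adjusted p = 0.921) turned direction; with the block and an estimated correlation the immediate early list had an adjusted p of 0.474.

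Turned directions in other fits were as follows, with log2 differences for genes and adjusted p for lists. With no filter the interferon receptor list turned (0.999), with a mean CPM above 1 the clock list (0.974), with limma-voom Mbp (0.012), with fry the synaptic (0.972) and clock (0.972) lists, and without shared members the clock list (0.804). With the striatal covariate Ifngr1 (−0.011) and the glutamatergic (0.590), synaptic (0.0721) and clock (0.138) lists turned, and the lists of myelin (5.54e-15), oligodendrocyte precursors (0.0225), astrocytes (0.0353) and ribosomal proteins (0.00127) were called lower and GABA genes (0.0165) higher; with an estimated correlation the covariate fit called 0 lists (0.672 for myelin). Without the 3 high-striatal libraries, where single-housed replicate 3 alone stands for its group, Socs1 (0.070), Abat (−0.059), Gad2 (−0.017), Actn2 (−0.058), Bgn (−0.023), Cdhr1 (−0.085), Irf1 (0.11), Fkbp5 (−0.14) and Gad1 (−0.044) turned, as did the lists of type I interferon response (0.992), microglia (0.462), astrocytes (0.992), pericytes (0.959), choroid plexus (0.0139), striatal markers (0.110), hippocampus and thalamus (0.931), ionotropic glutamate receptors (0.931) and ribosomal proteins (0.579).

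With 1 library left out, log2 differences that changed sign ranged from −0.29 to 0.076 for Olig2, −0.33 to 0.24 for Olig1, −0.026 to 0.17 for Ifngr1, −0.048 to 0.068 for Ifngr2, −0.19 to 0.032 for Irf1, −0.034 to 0.11 for Fkbp5, −0.016 to 0.091 for Gad1 and −0.31 to 0.45 for Mbp. Adjusted p of lists whose direction turned ranged from 0.697 to 0.926 for interferon receptors, 0.0116 to 0.652 for GABA genes, 0.00117 to 0.563 for myelin, 0.220 to 0.740 for oligodendrocyte precursors, 0.00365 to 0.668 for microglia, 0.0226 to 0.629 for pericytes, 0.0139 to 0.904 for glutamatergic markers, 0.00117 to 0.862 for synaptic genes, 0.0182 to 0.967 for ionotropic receptors, 0.0466 to 0.899 for clock genes, 1.11e-12 to 0.873 for oxidative phosphorylation and 1.86e-08 to 0.415 for ribosomal proteins.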

Other observations

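The genes singled out here were chosen after their values were seen, and so were the tests of group-housed replicate 1 and of housing alone for the striatal markers. The immediate early genes did not move as 1 block within the group-housed mice. Group-housed replicate 1 had the highest level of all 6 libraries for 11 of the 26 genes, among them Npas4, an activity-dependent transcription factor gene (69.4 CPM against 20.1 and 18.0 in group-housed replicates 2 and 3), Arc (359 against 141 and 157), Fos (52.0 against 23.0 and 33.2) and Junb (94.3 against 38.9 and 62.6). For 9 genes it lay below both other group-housed libraries, among them Egr3 (51.6 against 96.4 and 102 CPM), Homer1, a postsynaptic scaffold gene (107 against 205 and 193), Bdnf, a neurotrophin gene (36.4 against 51.5 and 51.5), and Egr1 (382 against 500 and 482). Group-housed replicate 1 lay below at least 1 single-housed library for 8 of the 26 genes. Its Homer1 level was below every single-housed library (132 to 176 CPM). Npas4 in group-housed replicates 2 and 3 lay near the single-housed range (14.3 to 19.4 CPM). Nptxr was at 6.74 ± 0.774 CPM in single-housed and 17.1 ± 7.09 CPM in group-housed libraries (SD, n = 3 each), and of the group-housed libraries replicate 1 was again the low one (9.17 against 20.9 and 20.8 CPM of the total).

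Myelin genes varied widely between libraries of the same housing, with the highest list means in the libraries with high striatal markers (single-housed replicates 1 and 2 and group-housed replicate 1). Their list mean was 6.62, 6.55 and 5.65 log2 CPM in single-housed replicates 1, 2 and 3 and 6.96, 5.64 and 6.22 in group-housed replicates 1, 2 and 3, and Mbp ranged from 622 to 1738 CPM. The adult beta-globin gene listed as Beta-s, a marker of red blood cells, was at 15.9 CPM of the total in group-housed replicate 1 and 1.25 to 6.79 in the others, and the erythroid haem synthesis gene Alas2 at 2.01 against 0.182 to 0.778. Fibroblast markers of the meninges had their lowest list mean in the same library, 3.19 against 3.72 to 4.04 log2 CPM. In 865 Reactome sets, 0 passed; the smallest p belonged to laminin interactions, whose 28 genes had a median log2 difference of 0.09 (adjusted p = 0.0769; 0.993 with an estimated correlation).

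Immediate early genes were lower in single-housed mice. If striatal tissue in the samples were the cause, adjusting for it would bring the housing difference to about 0. With the striatal list mean as a covariate it was −0.63 (SE 0.128, 3 residual degrees of freedom), which argues against that share as the whole cause. The striatal list mean only stands in for the share of striatal tissue, which was not measured. In that fit the immediate early list had a camera adjusted p of 0.108 with an estimated correlation. The direction did not rest on group-housed replicate 1 alone. Without it, every single-housed list mean lay below both remaining group-housed ones, but so few libraries cannot exclude chance. The list test (camera) without it had an adjusted p of 4.44e-19 with the preset correlation and 0.145 with an estimated one. That test cannot decide whether this library made the difference, because with the preset correlation it also passes in other splits. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave a list p as small (−log10 p of 26.8 against at most 4.21 in the other splits), although the list also passed with the preset correlation in 5 of the 9 other splits (smallest adjusted p = 3.24e-04); 10 splits are too few for a share under 0.05. Chance therefore stays open, as do housing itself and a difference in handling or in the order of tissue collection, which the labels do not record. No test here separates these. Only the striatal list mean was used as a covariate, not other differences between libraries such as those in red blood cell genes. Myelin list means were highest in the same libraries as the striatal list means, and were not adjusted for separately. Depth and the number of genes with a count, both higher in each single-housed library, also went with housing.

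Striatal markers were high in single-housed replicates 1 and 2 and group-housed replicate 1. Of 7 striatal genes outside the fixed list, all 7 of which had counts in every library, 6 were higher in each of those 3 libraries than in any other, such as Adcy5 (456, 262 and 239 CPM against 151 to 162) and Rasgrp2 (67.4, 35.9 and 34.0 against 13.7 to 16.3); the exception was Arpp21. A candidate explanation is that the dissected piece held some striatum in these libraries. The abundant striatal gene Penk followed the same libraries (318, 164 and 171 against 52.9 to 57.9 CPM of the total). The 7 genes varied together (estimated correlation 0.93), and the 3 libraries were picked by striatal markers. These values therefore cannot tell striatal tissue from a shared change in the expression of striatal genes. The myelin list mean was also higher in those 3 libraries (6.62, 6.55 and 6.96 log2 CPM) than in the others (5.65, 5.64 and 6.22). The difference between these libraries was therefore not confined to striatal genes. The astrocyte list mean did not separate them (7.37, 7.26 and 7.44 against 7.32, 7.24 and 7.39). Which tissue the myelin difference came from was not tested. Group-housed replicate 1 lay 1.52 log2 units above the next group-housed library, against a difference of 0.89 between the group means, but this is 1 library, picked because it was high, so a part of housing stays open. The split that puts these 3 libraries against the rest called 291 genes where housing and the other 8 splits called 0, a structure of the samples that, as the libraries were picked by their markers, is no separate support for its source.

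Because housing called 0 genes, 10 of 10 splits called at least as many by construction, and 10 splits allow no share under 0.05. Of the same 10 splits, 5 called at least as many gene lists as the 9 called for housing with the preset correlation, and the highest other called 16, again with too few splits for a share under 0.05.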
